A study of Homo sapiens with 15 samples.

How the data were processed

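RNA was sequenced from U2OS cells in 6 groups, Nutlin or DMSO in asynchronous, non-released and S-phase cells, with 15 libraries in all. Per the labels' protocols, cells were blocked with 2 mM thymidine for 16 h, left without it for 8 h and blocked again for 16 h, and Nutlin was added 4 h before release or before a continued block. S-phase cells were harvested 4 h after release with Nutlin kept in the medium. How long asynchronous cells were given Nutlin is not given in the sources used here. The dose of 10 µM lost its unit prefix in the labels and is read here as micromolar. Libraries were made from 1000 ng of RNA with a TruSeq kit and read as single reads of 50 nt, per the labels' protocols, and the strand is not given in the sources used here. Groups were taken from the library labels, and the labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples.

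The values are variance-stabilised, on a log2 scale at high expression, as deposited by the authors in 1 table of 23368 genes by 15 libraries. Differences on this scale are compressed at low read numbers, where voom gives larger ones. The submitters' processing notes name CASAVA 1.8.2, TopHat 0.9, HTSeq, DESeq2 1.10.1 and the human build hg19, and do not say what each did. Annotation is not given in the sources used here. GENCODE v29 on GRCh38 was used here only for gene names, transcript length and GC content. Builds differ, so no coordinates are printed. Of the row names, 19998 are current symbols, 2083 older symbols and 1287 without a match, and symbols are printed as in the table. A spreadsheet had turned 28 names into dates, 2 of which stand for 2 genes each, and these stayed under the names in the table. No mitochondrially encoded gene of the 15 listed is in the table.

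Reads were recovered by inverting the transformation. All libraries share a lowest value of 4.859, that of a gene with 0 reads, and every value above it in 14 libraries lay within 0.05 of a whole read after scaling by 1 factor per library. In the library labelled DMSO S-phase replicate 3 this held for 99.21% of genes. Reads assigned to genes, in M reads and in the order of replicate numbers, came to 16.98, 17.91 and 15.64 (DMSO asynchronous), 23.34, 11.89 and 15.44 (Nutlin asynchronous), 18.94 and 23.38 (DMSO non-released), 15.3 and 20.19 (Nutlin non-released), 19.02, 6.05 and 15.93 (DMSO S-phase), and 12.05 and 10.25 (Nutlin S-phase). The median was 15.93, against 30 planned per the labels' protocols. A gene with 0 reads lies under 0.128 to 0.496 counts per M reads by library, M standing for mega, the limit being 3 reads, which covers counting error only. The ribosomal precursor gene RN45S took 0.1 to 3.7% of reads.

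Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 15 libraries, moderated by eBayes with a mean-variance trend (prior degrees of freedom 4.66). Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within each comparison, and adjusted p under 0.05 counted as a call. Of all genes, 14298 with at least 2 libraries 1 unit or more above the lowest value were tested. The 9 comparisons were Nutlin against DMSO in each state, the 3 differences between those responses, and the 3 differences between states in DMSO. Because all groups share 1 spread per gene, a single library far from its group raises the p-values of every comparison for the genes in which it differs. Each state has DMSO libraries of its own, so the 3 Nutlin comparisons share no control.

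Gene lists were written before the data were examined: 4 of p53 targets (arrest and feedback, cell death, DNA repair and deoxynucleotide supply, metabolism and autophagy), genes of G1/S, of G2 and mitosis, of origins and the replisome, of fork protection, of nucleotide synthesis, histones, sterol synthesis, interferon response, inflammatory cytokines, amino acid and unfolded protein stress, ribosome biogenesis and MYC targets, immediate early genes, and markers of blood, epithelial, and bone and mesenchymal cells. Markers of luminal breast, colon and liver cells were added after the data were seen and are used only to describe single libraries. Lists were tested against all other genes with limma's camera at its preset correlation of 0.01, 171 tests of 19 lists adjusted together, of which 70 passed. With a correlation estimated from the residuals 3 passed, the arrest and feedback targets under Nutlin in each state. Without both libraries that stand apart 85 passed, and 12 with an estimated correlation: the arrest, cell death and metabolism targets under Nutlin in each state, the arrest targets in the difference between non-released and asynchronous responses, and interferon genes in non-released and in S-phase against asynchronous cells. Members were also adjusted over the list alone.

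Genes named in the text follow a rule set before their values were seen. In the 6 comparisons of groups these are the 10 largest positive and 10 largest negative differences that pass the test with no overlap between the libraries of both groups, and 5 and 5 in the differences between responses. Up to 4 members of each list with the smallest p are added, and MDM2, CDKN1A, CCNE2, CCNB1 and CDC20 as checks of the labels. The text prints a part of them, and some are not reported here. Outside the rule, and chosen after their values were seen, are the markers given per library, GDF15, XPC in S-phase cells, the examples among genes shared by all 3 states, and the 3 genes called for a difference between responses in 13 libraries.

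Alternatives set before the data were examined were a fit to the compared groups alone, no trend, a robust fit, no filter (20110 genes), a stricter filter (11497 genes, mean at least 2 units above the lowest value), equal medians, quantile normalization, a replicate block, each library left out in turn, voom on the recovered reads, and a difference of at least 1. Leaving out both libraries that stand apart was added after seeing the data, as were library weights. The test was also run on simulated data (5 runs, 100 genes changed per fold size of 14298). Their spread came from the 13 libraries other than both that stand apart, and no simulated library stood apart. There the test found 61, 46.6 and 56.8% of changes of 1.5-fold for Nutlin in asynchronous, non-released and S-phase cells. Of changes of 3-fold it found 92.8, 90.4 and 92.8%. Of the calls 4.7, 4.3 and 5.9% fell on unchanged genes. For the states these were 60.2, 56.6 and 50.2%, 93.2, 90.2 and 92.6%, and 4.5, 2.1 and 3.8%, in the order S-phase against asynchronous, non-released against asynchronous, and S-phase against non-released cells. These shares leave out the effect of libraries that stand apart, so they do not describe the test on all 15 libraries, which includes both. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reading, checks and figures.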

Results

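RNA sequencing was used to measure gene expression in U2OS cells, an osteosarcoma line that carries wild-type p53. Nutlin, given at 10 µM, is an antagonist of MDM2, the ubiquitin ligase that keeps p53 low. DMSO was the vehicle control. Cells were harvested in 3 states: asynchronous growth, arrest by a double thymidine block without release (non-released cells), and S-phase 4 h after release from that block. Asynchronous cells gave 3 DMSO and 3 Nutlin libraries, non-released cells 2 and 2, and S-phase cells 3 DMSO and 2 Nutlin libraries, 15 in all. Reads assigned to genes, recovered from the deposited values, ran from 6.05 to 23.38 M reads per library. Values are on the deposited log2 scale, differences are on that scale with their standard error (SE), and n is the number of libraries per group.

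Transcripts of the direct p53 targets CDKN1A, which encodes the kinase inhibitor p21, and MDM2, which feeds back on p53, served as checks of the Nutlin label. In non-released cells CDKN1A averaged 13.93 ± 0.04 (SD, n = 2) with Nutlin and 12.49 ± 0.06 (SD, n = 2) with DMSO. MDM2 averaged 14.81 ± 0.03 and 13.09 ± 0.02. In S-phase cells CDKN1A averaged 14.02 ± 0.22 (SD, n = 2) with Nutlin and 12.02 ± 0.22 (SD, n = 3) with DMSO. MDM2 averaged 14.66 ± 0.08 and 12.71 ± 0.19 there. In asynchronous cells the 3 Nutlin libraries lay at 13.58, 13.51 and 13.59 for CDKN1A. DMSO replicates 1 and 2 lay at 11.47 and 11.45, and the library labelled DMSO asynchronous replicate 3 at 14.10, above every Nutlin asynchronous library. MDM2 behaved alike, at 12.44, 12.50 and 14.77 in the DMSO libraries and from 14.55 to 14.71 in the Nutlin libraries.

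The library labelled DMSO asynchronous replicate 3 also carried transcripts that the other 14 libraries nearly lacked. Of 18 measured epithelial markers, 13 were highest in that library, where chance gives 1.2. KRT19, a keratin of simple epithelia, stood at 7826.1 normalised reads there and at most 33.9 elsewhere. CDH1, the epithelial cadherin, stood at 3505.5 against at most 98.9. Of 13 measured markers of luminal breast cells, 12 were highest there, among them the oestrogen receptor gene ESR1 at 1434.1 reads against at most 22.6. Some of the 12 were abundant elsewhere too, such as KRT8 and KRT18 at 15142.6 and 10509.5 reads against at most 8762.7 and 8967.5. The library labelled DMSO S-phase replicate 2 was the shallowest, at 6.05 M reads. Its values correlated with its own group at a mean of r = 0.9773 across genes, the lowest of the 15 libraries after DMSO asynchronous replicate 3 at 0.9753. Genes are not independent replicates, so these correlations only describe the libraries. Counts and list values below come from all 15 libraries. An alternative added after the data were seen leaves out both of these libraries, and a part of its values, from 13 libraries, is given beside them or in the closing section. DMSO asynchronous replicate 3 was set apart by its high p53 targets. Where DMSO asynchronous cells are compared, p-values of p53 targets without that library are therefore no independent test.

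**Figure D1:**
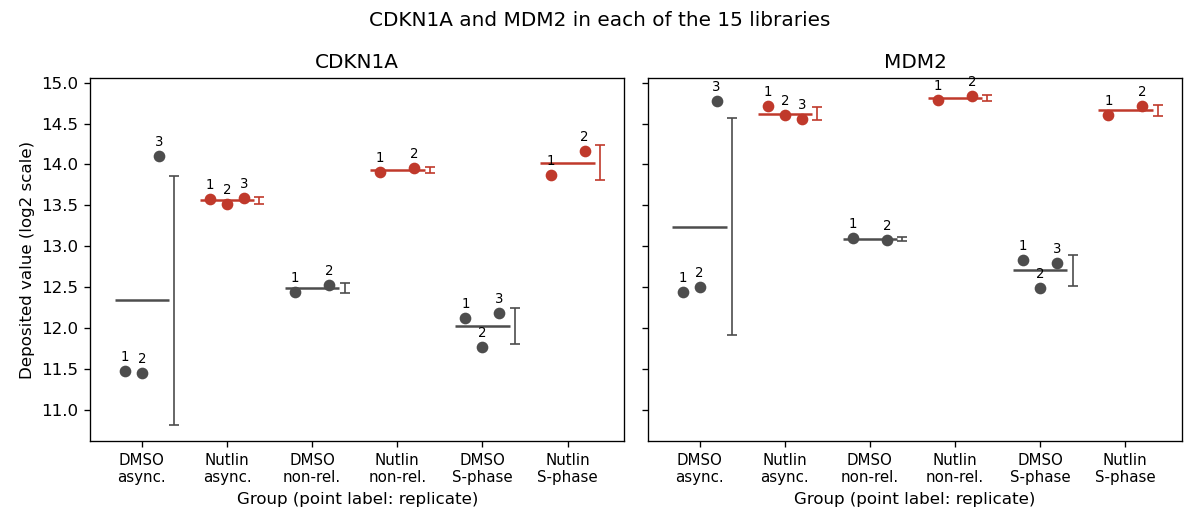
Deposited values (log2 scale, vertical axis) of CDKN1A and MDM2 in each of the 15 libraries by group, with replicate numbers over the points, group means as lines and standard deviations as bars. The library labelled DMSO asynchronous replicate 3 stands at 14.10 for CDKN1A and 14.77 for MDM2, above all 3 Nutlin asynchronous libraries.

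**Figure D2:**
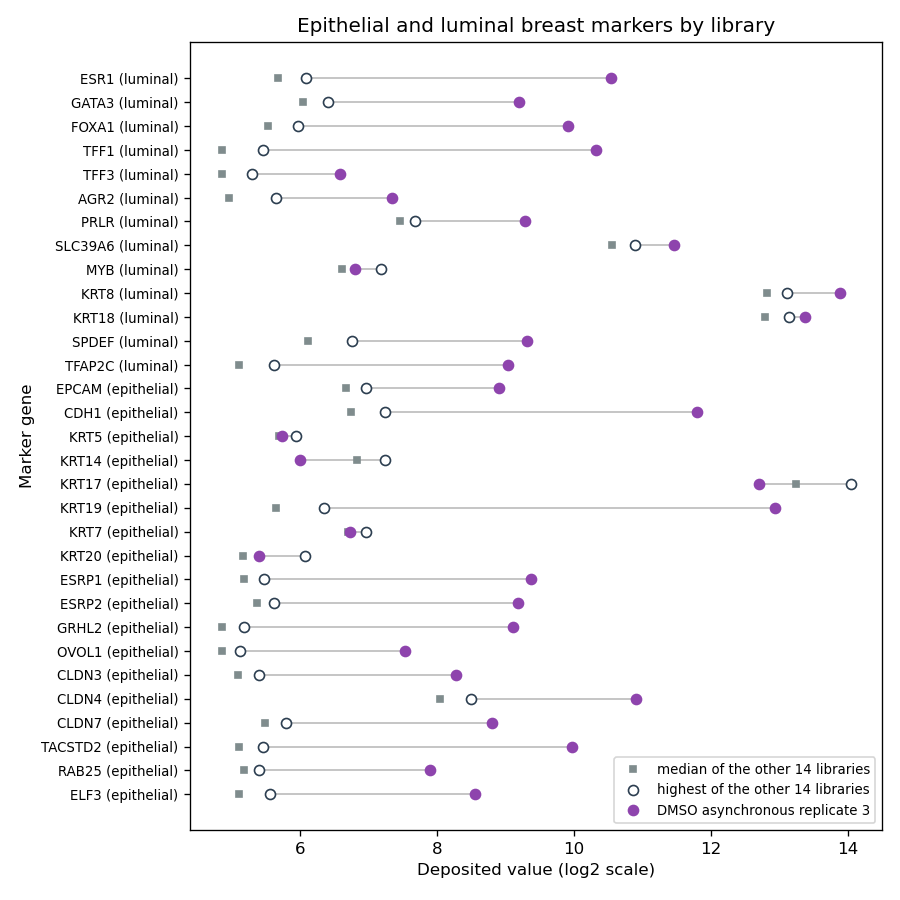
Deposited values (log2 scale, horizontal axis) of 31 epithelial and luminal breast marker genes (vertical axis) in the library labelled DMSO asynchronous replicate 3, beside the highest and the median of the other 14 libraries. KRT19 stands at 12.94 in that library and at most 6.35 in the others, and 6 of the 31 markers (MYB, KRT5, KRT14, KRT17, KRT7 and KRT20) were not highest there.

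The comparison of Nutlin with DMSO in asynchronous cells addressed which genes p53 activity raises or lowers in a cycling population. The surface adhesion gene PVRL4 (2.28 ± 0.31 SE, n = 3 and 3, adjusted p = 0.00076) and the antiproliferative p53 target BTG2 (1.88 ± 0.24, adjusted p = 0.00041) rose with Nutlin. So did the ephrin gene EFNB1 (1.77 ± 0.11, adjusted p = 8.93e-07) and the death receptor gene FAS (1.74 ± 0.15, adjusted p = 1.34e-05). The chemokine gene CCL3 rose by 2.45 ± 0.27 (adjusted p = 0.000123), and by 4.01 with voom, with 329 ± 189 (SD) against 22 ± 15.3 normalised reads. Its neighbour in the chemokine family, CCL4, averaged 46.8 normalised reads with Nutlin and lay at the lowest value of the table in all 3 DMSO libraries, so that no fold is given. CCL3 and CCL4 each have near-identical copies in the genome, which makes their values uncertain. The transcription factor gene E2F2, which drives entry into S-phase, fell by 1.00 ± 0.15 (adjusted p = 0.00122) and the mismatch repair gene MSH6 by 0.67 ± 0.09 (adjusted p = 0.000618). ZNF367 and FAM111B fell by 0.81 ± 0.11 and 0.76 ± 0.10 (adjusted p = 0.000585 and 0.000593).

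The lists of known p53 targets had positive medians with Nutlin in asynchronous cells. Among them, only the arrest and feedback list passed with an estimated correlation when all libraries were used. Of 23 measured targets that act in cell cycle arrest and feedback, 13 rose over all genes and 19 adjusted over the list alone, with a median difference of 0.84 (adjusted p = 4.89e-28; adjusted p = 0.0111 with an estimated correlation). TRIM22 (1.43 ± 0.09), the stress sensor SESN2 (1.29 ± 0.11), PLK3 (1.04 ± 0.09) and CSF1 (1.44 ± 0.16) had the smallest p. Of 18 targets that act in cell death, 10 rose over all genes and 13 adjusted over the list alone (median 0.66, adjusted p = 2.07e-16; adjusted p = 0.0561 with an estimated correlation). Smallest p were those of FAS, TNFRSF10B, PIDD (1.43 ± 0.13) and BAX (0.70 ± 0.09). Of 19 targets in metabolism and autophagy, 9 rose over all genes and 12 adjusted over the list alone (median 0.52, adjusted p = 1.31e-12; adjusted p = 0.062 with an estimated correlation). C12orf5, the older symbol of TIGAR, rose by 1.27 ± 0.08 and the ferredoxin reductase gene FDXR by 1.32 ± 0.10. Of 12 targets in DNA repair and deoxynucleotide supply, 5 rose over all genes, and adjusted over the list alone 5 rose and 3 fell (median 0.16, adjusted p = 0.00363; adjusted p = 0.404 with an estimated correlation). These 5 included RRM2B, the p53-inducible subunit of ribonucleotide reductase (1.47 ± 0.17, adjusted p = 0.000165), the translesion polymerase gene POLH (1.16 ± 0.15) and the nucleotide excision repair genes DDB2 (0.79 ± 0.12) and XPC (0.84 ± 0.15). MDM2 (1.38 ± 0.42, adjusted p = 0.135) and CDKN1A (1.22 ± 0.49, adjusted p = 0.305) did not pass the test in the 6 libraries. Without DMSO asynchronous replicate 3 they rose by 2.15 (adjusted p = 1.39e-07) and 2.10 (adjusted p = 3.55e-07). Leaving out DMSO replicate 1 or 2 instead gave CDKN1A at 0.78 and 0.77 (adjusted p = 0.541 and 0.632). Over all alternatives adjusted p ran from 2.3e-10 to 0.401 for MDM2 and from 7.59e-10 to 0.632 for CDKN1A.

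The lists of cell cycle and DNA replication genes had negative medians with Nutlin in asynchronous cells. Of 30 genes of the G1/S transition under E2F control, 16 fell over all genes and 26 adjusted over the list alone (median -0.42, adjusted p = 7.92e-24; adjusted p = 0.0561 with an estimated correlation). ATAD2 (-0.52 ± 0.09) and the initiation factor gene MCM10 (-0.51 ± 0.10) fell beside MSH6 and E2F2. Of 47 genes of origin licensing and the replisome, 5 fell and 1 rose over all genes, and 12 fell and 2 rose adjusted over the list alone (median -0.19, adjusted p = 1.87e-08; adjusted p = 0.404 with an estimated correlation). ORC1 (-0.55 ± 0.09), MCM6 (-0.52 ± 0.10) and MCM3 (-0.55 ± 0.11) of the origin licensing machinery fell, and the polymerase clamp gene PCNA, itself a p53 target, rose by 0.50 ± 0.10 (adjusted p = 0.0155). Of 44 genes of fork protection, fork remodelling and the replication checkpoint, 3 fell over all genes and 7 adjusted over the list alone (median -0.09, adjusted p = 0.000248; adjusted p = 0.282 with an estimated correlation). They included the kinase gene WEE1 (-0.38 ± 0.08) and the checkpoint adaptor gene CLSPN (-0.42 ± 0.09). Of 45 genes of G2 and mitosis, 1 (HJURP, -0.38 ± 0.09) fell over all genes and 14 adjusted over the list alone (median -0.27, adjusted p = 4.76e-14; adjusted p = 0.381 with an estimated correlation). Of 42 replication-dependent histone genes, 1 fell over all genes and adjusted over the list alone, HIST1H1A (-0.86 ± 0.19, adjusted p = 0.029), with a list median of -0.28 (adjusted p = 2.73e-07; adjusted p = 0.612 with an estimated correlation). Without both libraries that stand apart, 22 arrest and feedback targets rose, and 20 replisome, 8 fork, 27 mitotic and 17 histone genes fell. The medians of the repair targets and of histone genes were then 0.29 and -0.53. Per library the histone median was 11.59, 10.85 and 10.35 in DMSO asynchronous replicates 1 to 3. In Nutlin asynchronous replicates 1 to 3 it was 10.95, 10.53 and 10.53. Replicate 1 was highest in both treatments, and DMSO replicate 2 lay under Nutlin replicate 1, so the histone fall depends on which replicates are kept. CCNE2, the cyclin that starts S-phase, fell by 0.56 ± 0.12 (adjusted p = 0.0241). The mitotic genes CCNB1 (-0.25 ± 0.14, adjusted p = 0.547) and CDC20 (-0.36 ± 0.11, adjusted p = 0.148) did not pass the test with 15 libraries. With 13 they fell by 0.37 and 0.44 (adjusted p = 0.0193 and 0.0172). Over all alternatives adjusted p ran from 0.0193 to 0.852 for CCNB1 and from 0.0172 to 0.549 for CDC20.

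Of 16 inflammatory cytokine and NF-kB feedback genes, 2 rose over all genes and 5 adjusted over the list alone (median 0.34, adjusted p = 4.53e-07; adjusted p = 0.293 with an estimated correlation). These 2 were TNFAIP3 (0.79 ± 0.12) and BIRC3 (0.77 ± 0.17), which restrain NF-kB signalling and apoptosis. Of 26 genes of amino acid and unfolded protein stress, 4 rose under either adjustment (median 0.08, adjusted p = 0.00424; adjusted p = 0.155 with an estimated correlation). They were SESN2, ATF3 (1.16 ± 0.14), HERPUD1 (0.48 ± 0.09) and PPP1R15A (0.56 ± 0.13), of which SESN2 and ATF3 are p53 targets as well. No member of the interferon response list passed (median -0.17, adjusted p = 0.0176; adjusted p = 0.404 with an estimated correlation, 0.828 under the stricter filter, and a median of -0.08 with 0.255 without both libraries that stand apart). None of 31 genes of nucleotide synthesis, 23 of sterol synthesis or 27 immediate early genes passed over all genes. Their list tests gave adjusted p of 0.487, 0.297 and 0.131, and without both libraries that stand apart 0.0193 for nucleotide synthesis, at a median of -0.11 (adjusted p = 0.495 with an estimated correlation). Of 30 genes of ribosome biogenesis and MYC targets 1 fell, NOLC1 (-0.33 ± 0.07; list median -0.02, adjusted p = 0.558). Without both libraries that stand apart that list had a median of -0.10 (adjusted p = 0.0231; adjusted p = 0.555 with an estimated correlation). The median of the 8 epithelial markers that entered the test was -0.52, and -0.02 without both libraries that stand apart (adjusted p = 0.32 and 0.972). Blood cell markers and bone and mesenchymal markers had medians of 0.14 and 0.07 (adjusted p = 0.308 and 0.105).

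In all, 351 of 14298 genes passed limma's test in asynchronous cells, 273 higher and 78 lower with Nutlin. Of these 346 were among the 888 genes (536 higher, 352 lower) called without both libraries that stand apart. In the compared groups alone 202 were called, 180 higher and 22 lower, and CCNE2 (adjusted p = 0.0936) was not. Leaving out DMSO replicate 2, Nutlin replicate 1 or Nutlin replicate 2 gave 207, 170 and 195 genes, of which 28, 13 and 22 were lower. HIST1H1A and CCNE2 lost their calls without any one of the 6 libraries but the library labelled DMSO asynchronous replicate 3 (adjusted p from 0.0613 to 0.129 and from 0.0523 to 0.101).

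The same comparison in non-released cells asked what p53 does to cells held by the thymidine block at the start of S-phase. The riboflavin transporter gene GPR172B (1.69 ± 0.19 SE, n = 2 and 2, adjusted p = 0.00106) and the cadherin genes CDH10 (1.45 ± 0.15, adjusted p = 0.00053) and PCDH17 (1.32 ± 0.10, adjusted p = 8.29e-05) rose with Nutlin. The cytokine gene CSF1 (1.47 ± 0.20, adjusted p = 0.00262) and FAS (1.28 ± 0.18, adjusted p = 0.00295) rose too. PVRL4 rose by 1.99 ± 0.38 (adjusted p = 0.0224). The protocadherin gene PCDH18 fell by 1.04 ± 0.15 (adjusted p = 0.00339) and the neural proto-oncogene MYCN, near the bottom of the scale at 5.96 ± 0.11 (SD, n = 2) in DMSO, by 0.61 ± 0.12 (adjusted p = 0.0319). With voom MYCN stood at -2.22, from 3.5 against 18 normalised reads, and CDH10 at 2.19.

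Of the 23 arrest and feedback targets, 7 rose over all genes and 16 adjusted over the list alone in non-released cells (median 0.70, adjusted p = 3.29e-26; adjusted p = 0.0111 with an estimated correlation). PLK3 (1.08 ± 0.11), CSF1, GADD45A (0.91 ± 0.15) and TRIM22 (0.70 ± 0.12) had the smallest p. Of the 18 cell death targets 7 rose over all genes and 12 adjusted over the list alone (median 0.69, adjusted p = 1.01e-19; adjusted p = 0.0561 with an estimated correlation), among them TNFRSF10B (0.99 ± 0.12) and BAX (0.64 ± 0.11). Metabolism and autophagy targets counted 6 of 19 over all genes and 10 adjusted over the list alone (median 0.66, adjusted p = 3.59e-15; adjusted p = 0.0561 with an estimated correlation). DNA repair and deoxynucleotide supply counted 1 of 12, RRM2B (1.06 ± 0.20, adjusted p = 0.0224), and 5 adjusted over the list alone (median 0.16, adjusted p = 0.000392; adjusted p = 0.34 with an estimated correlation). Immediate early genes, which respond within minutes to growth and stress signals, counted 4 of 27 higher over all genes and 14 adjusted over the list alone (median 0.51, adjusted p = 9.23e-19; adjusted p = 0.0561 with an estimated correlation). The 4 were FOS (1.27 ± 0.18), CYR61 (1.09 ± 0.21), DUSP5 (1.32 ± 0.28) and the survival gene MCL1 (0.51 ± 0.11). Of 16 inflammatory genes, BIRC3 (1.11 ± 0.21) and TNFAIP3 (0.68 ± 0.15) rose over all genes and 7 rose adjusted over the list alone (median 0.45, adjusted p = 2.01e-11; adjusted p = 0.137 with an estimated correlation).

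The cell cycle lists had medians nearer to 0 in blocked cells. None of 30 G1/S genes passed over all genes or over the list alone, at a median of -0.16 (adjusted p = 8.65e-05; adjusted p = 0.404 with an estimated correlation). None of 47 replisome genes passed either (median -0.07, adjusted p = 0.0216; adjusted p = 0.813 with an estimated correlation). The G2 and mitosis, fork, histone and nucleotide lists gave adjusted p of 0.131, 0.591, 0.351 and 0.374. Sterol synthesis (median -0.17, adjusted p = 0.0258) and interferon genes (median -0.08, adjusted p = 0.0317) had no member past the test, and their calls were lost with an estimated correlation (adjusted p = 0.724 and adjusted p = 0.452 with an estimated correlation). The interferon call was also lost under the stricter filter (median -0.02, adjusted p = 0.741) and with a replicate block. The 131 genes called by limma were 125 higher and 6 lower. All of them were among the 459 genes (399 higher, 60 lower) called without both libraries that stand apart. There 16 arrest, 14 cell death, 13 metabolism, 5 repair and 12 immediate early genes rose. Leaving out DMSO replicate 1 or 2 gave 29 and 39 genes, and Nutlin replicate 1 or 2 gave 43 and 22. The tool voom on the recovered reads gave 227 (203 higher, 24 lower), and the compared groups alone 637 (521 higher, 116 lower). PVRL4, DUSP5 and MYCN lost their calls without any one of the 4 libraries (adjusted p from 0.13 to 0.261, 0.0833 to 0.467 and 0.143 to 0.403). CSF1 and PCDH18 lost them without DMSO replicate 1 (0.0578 and 0.0803) or Nutlin replicate 2 (0.0532 and 0.0834), and FAS without Nutlin replicate 2 (0.0514). MDM2 (1.73 ± 0.52, adjusted p = 0.22) and CDKN1A (1.44 ± 0.60, adjusted p = 0.597) did not pass with 15 libraries, whose shared spread includes DMSO asynchronous replicate 3. In the compared groups alone they passed (adjusted p = 1.99e-05 and 3.25e-05). With 13 libraries they rose by the same 1.73 and 1.44 (adjusted p = 2.39e-08 and 6.53e-07). Over all alternatives adjusted p ran from 2.39e-08 to 0.929 for MDM2 and from 6.53e-07 to 1 for CDKN1A.

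The title of the series links p53 to the processivity of replication forks, and S-phase cells are those in which forks run. Nutlin again raised PVRL4 (2.55 ± 0.35 SE, n = 2 and 3, adjusted p = 0.00102), BTG2 (2.15 ± 0.27, adjusted p = 0.000555) and GPR172B (1.93 ± 0.17, adjusted p = 4.52e-05). It also raised FAS (1.54 ± 0.16, adjusted p = 0.000192), EFNB1 (1.53 ± 0.12, adjusted p = 1.72e-05) and RGL1, an exchange factor for Ral GTPases (1.56 ± 0.12, adjusted p = 1.14e-05). RRM2B rose by 1.46 ± 0.19 (adjusted p = 0.000674) and PCNA by 0.83 ± 0.11 (adjusted p = 0.000962). TFAP4, a transcription factor gene downstream of MYC, fell by 0.68 ± 0.13 (adjusted p = 0.0123) and the DNA methyltransferase gene DNMT3B by 0.60 ± 0.14 (adjusted p = 0.0486).

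Of the 23 arrest and feedback targets, 14 rose over all genes and 19 adjusted over the list alone in S-phase (median 0.84, adjusted p = 7.92e-24; adjusted p = 0.0111 with an estimated correlation). Smallest p there were those of TRIM22 (1.05 ± 0.11), SESN2 (1.13 ± 0.13), BTG2 and GADD45A (0.96 ± 0.14). Cell death targets counted 11 of 18 higher over all genes, and 13 higher and 1 lower adjusted over the list alone (median 0.72, adjusted p = 2.07e-16; adjusted p = 0.0561 with an estimated correlation). The survival factor gene TRIAP1 rose by 1.29 ± 0.16. Metabolism and autophagy targets counted 9 of 19 over all genes and 12 adjusted over the list alone (median 0.90, adjusted p = 1.34e-12; adjusted p = 0.062 with an estimated correlation). C12orf5 rose by 1.14 ± 0.09 and PRKAB1, a subunit of the energy sensor AMPK, by 0.90 ± 0.09. The repair and deoxynucleotide list counted 5 of 12 under either adjustment (median 0.17, adjusted p = 8.09e-05; adjusted p = 0.275 with an estimated correlation). They were RRM2B, DDB2 (0.91 ± 0.13), RAD51C (0.90 ± 0.14), POLH (0.96 ± 0.17) and XPC (0.80 ± 0.16). Replication genes gave few calls. PCNA was the only one of 47 replisome genes to pass (list median 0.01, adjusted p = 0.829). None of 44 fork protection genes (median -0.01, adjusted p = 0.783), 31 nucleotide synthesis genes (0.07, adjusted p = 0.704) or 30 G1/S genes (-0.08, adjusted p = 0.291) passed with limma. Nor did any of 45 genes of G2 and mitosis (-0.05, adjusted p = 0.288) or 42 histone genes (0.12, adjusted p = 0.243). Their counts without both libraries that stand apart were 1 replisome gene higher and 1 lower, 1 nucleotide gene higher and 0 in the other 4 lists. For the genes of G2 and mitosis the list test then gave a median of -0.14 (adjusted p = 0.000321; adjusted p = 0.588 with an estimated correlation). Inflammatory genes had a median of 0.21 (adjusted p = 0.00187; adjusted p = 0.562 with an estimated correlation), with 0 of 16 past the test over all genes and 2 adjusted over the list alone. The amino acid stress list had a median of 0.07 (adjusted p = 0.0482; adjusted p = 0.381 with an estimated correlation), with SESN2 and ATF3 (1.18 ± 0.15) higher over all genes. That list was no longer called without both libraries that stand apart (adjusted p = 0.124), under the stricter filter (0.0524) or after quantile normalization (0.0753), with medians of 0.03, 0.07 and 0.04. Immediate early genes had a median of 0.13 (adjusted p = 0.374), and 0.20 without both libraries that stand apart (adjusted p = 0.00656; adjusted p = 0.562 with an estimated correlation).

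The 286 genes called by limma in S-phase cells were 263 higher and 23 lower. Of these 283 were among the 563 (482 higher, 81 lower) called without both libraries that stand apart. The lower calls were few in other fits, 4 with voom (235 higher) and 0 in the compared groups alone (99 higher). Leaving out Nutlin replicate 1 or 2 gave 168 and 88 genes. Each of the 10 largest falls, TFAP4 and DNMT3B among them, lost its call without Nutlin replicate 1 or without Nutlin replicate 2 (adjusted p between 0.0766 and 0.519 where lost), TFAP4 only without the latter (0.146). MDM2 (1.96 ± 0.47, adjusted p = 0.0526) and CDKN1A (2.00 ± 0.55, adjusted p = 0.0927) missed the threshold with 15 libraries. In the compared groups alone they passed (adjusted p = 0.00631 and 0.00853), as they did with a replicate block (0.0218 and 0.0284), MDM2 also with equal medians (0.0423). They rose by 1.85 and 1.87 with 13 (adjusted p = 5.12e-09 and 1.85e-08). Over all alternatives adjusted p ran from 5.12e-09 to 0.265 for MDM2 and from 1.85e-08 to 0.323 for CDKN1A.

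**Figure D3:**
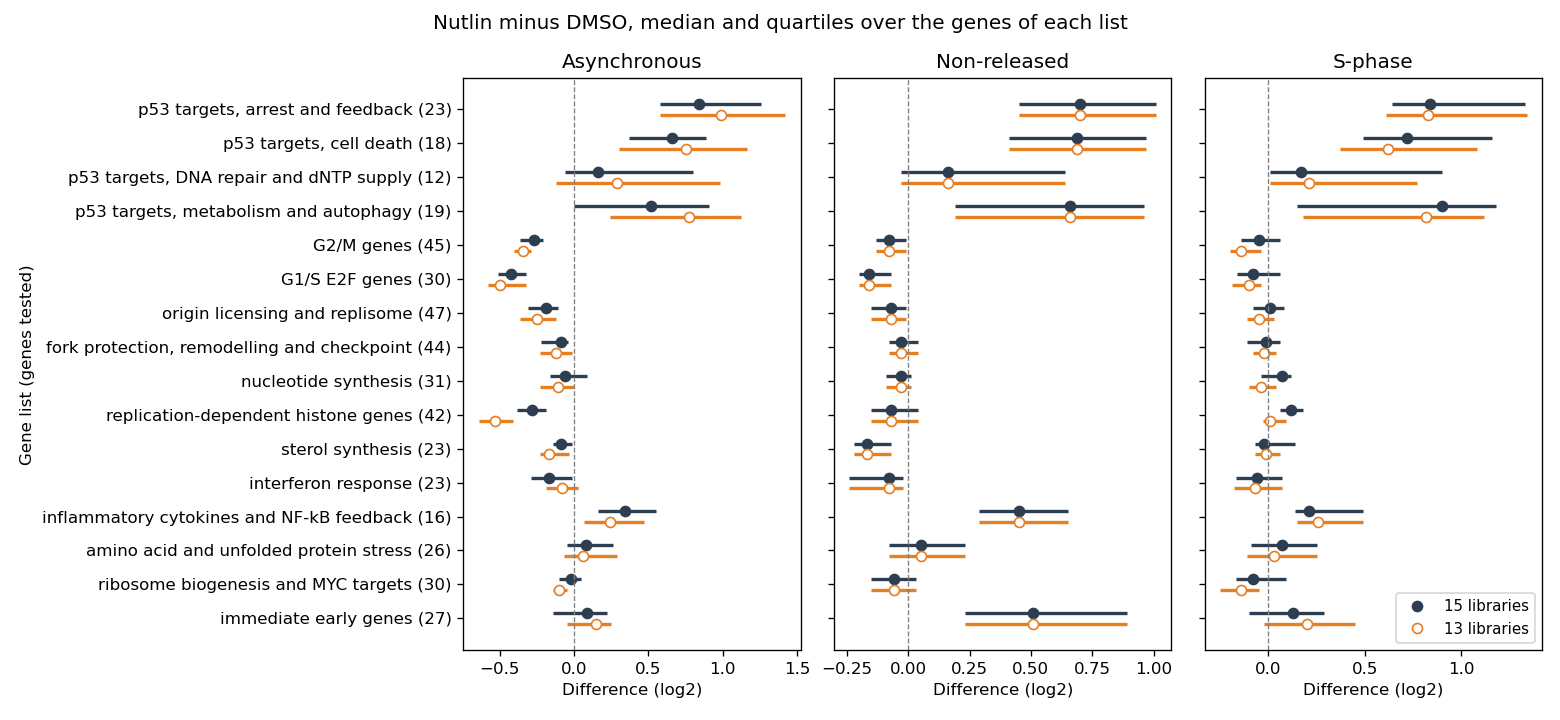
Median difference between Nutlin and DMSO (log2, horizontal axes) over the genes of each fixed list (vertical axis, number of genes tested in brackets) in the 3 cell states, with quartiles as bars, from all 15 libraries (filled) and from 13 (open). The 23 arrest and feedback targets have medians of 0.84, 0.70 and 0.84, and the 30 G1/S genes -0.42, -0.16 and -0.08.

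Genes that rose with Nutlin overlapped between the states. Of the 273 genes higher in asynchronous cells, 107 were also higher in non-released and 178 in S-phase cells, where independent lists would share 2.4 and 5. Non-released and S-phase cells shared 105 against 2.3. The numbers for independent lists are no measure of chance here. All 3 comparisons use the same spread per gene, so a gene with a small spread is called more readily in each. No gene was called in opposite directions in any pair of states. The 96 genes higher in all 3 states included the p53 targets FAS, BAX, TNFRSF10B, GADD45A, SESN2, ZMAT3, FDXR and RRM2B, and PCDH18 was lower in all 3. The S-phase call of PCDH18 was lost without any one DMSO S-phase library (adjusted p from 0.0509 to 0.0769 with limma). It was also lost after quantile normalization (0.056), with voom (0.0781) and in the compared groups alone (0.123). Without both libraries that stand apart 260 genes were higher and 5 lower in all 3 states. The pairs of states then shared 314 (asynchronous and non-released), 339 (asynchronous and S-phase) and 291 (non-released and S-phase) higher genes, against 15, 18.1 and 13.5 for independent lists.

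Whether the response to Nutlin differed between states was tested as the difference of differences. No single gene passed limma's test for S-phase against asynchronous, non-released against asynchronous or S-phase against non-released cells. At an unadjusted p under 0.05 there were 787, 155 and 321 genes. The smallest adjusted p were 0.444, 0.404 and 0.999, and voom on the recovered reads also gave 0 in each. As groups, the G1/S genes were lowered less in S-phase than in asynchronous cells (median difference of the responses 0.37, adjusted p = 1.97e-16; adjusted p = 0.0675 with an estimated correlation) and less in non-released than in asynchronous cells (0.27, adjusted p = 1.55e-19; adjusted p = 0.0561 with an estimated correlation). Replisome genes gave 0.21 (adjusted p = 7.17e-08; adjusted p = 0.404 with an estimated correlation) in S-phase and 0.14 (adjusted p = 2.76e-05; adjusted p = 0.576 with an estimated correlation) in non-released cells, each against asynchronous cells. Immediate early genes responded more in non-released than in asynchronous cells (0.47, adjusted p = 7.81e-19; adjusted p = 0.0561 with an estimated correlation) and less in S-phase than in non-released cells (-0.41, adjusted p = 6.22e-14; adjusted p = 0.0979 with an estimated correlation). Without both libraries that stand apart, 3 genes passed for non-released against asynchronous cells, all p53 targets that rose less in the blocked cells. They were BTG2 (-1.04, adjusted p = 0.00294), SESN1 (-0.78, adjusted p = 0.011) and TP53INP1 (-1.11, adjusted p = 0.00294), chosen after their values were seen. DMSO asynchronous replicate 3, left out there, lay above the mean of replicates 1 and 2 in all 3 (10.58 against 9.41, 10.1 against 8.93 and 12.48 against 8.39). Leaving it out by itself enlarges their rise in asynchronous cells, so these p-values are no independent test. TP53INP1 already stood higher with DMSO in non-released cells, at 10.43 and 10.46, than in asynchronous replicates 1 and 2, at 8.35 and 8.43. With Nutlin it lay at 11.51 and 11.45 in non-released cells and from 10.47 to 10.65 in asynchronous cells. Its smaller rise is therefore not a lower level under Nutlin, and how long asynchronous cells were given Nutlin is not known.

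The DMSO libraries show what the block and the release did without Nutlin, and check the labels of the cell states. In non-released against asynchronous cells, CCNE2 rose by 1.40 ± 0.13 (SE, n = 2 and 3, adjusted p = 1.46e-05). CDC20, the activator of the anaphase-promoting complex, fell by 1.26 ± 0.13 (adjusted p = 1.82e-05), and CCNB1, the mitotic cyclin, fell by 0.66 ± 0.16 (adjusted p = 0.00532; -0.42 after quantile normalization, adjusted p = 0.0239). The guanylate cyclase gene GUCY1A2 (2.41 ± 0.16), CRISPLD1 (2.22 ± 0.11) and RNF43, a brake on Wnt signalling (2.17 ± 0.20, and 3.64 with voom), rose. The pattern recognition gene PTX3 (-2.28 ± 0.24), the signalling adaptor TRAF1 (-2.01 ± 0.21) and the histone gene HIST1H2BJ (-2.29 ± 0.31) fell. Of 42 histone genes 33 fell over all genes and 35 adjusted over the list alone (median -1.16, adjusted p = 8.1e-14; adjusted p = 0.404 with an estimated correlation). Genes of ribosome biogenesis and MYC targets counted 26 of 30 lower under either adjustment (median -0.85, adjusted p = 4.41e-16; adjusted p = 0.147 with an estimated correlation). MYC itself stood at -1.65 ± 0.14 and the rRNA processing gene RRP12 at -1.39 ± 0.10. Interferon response genes counted 15 of 23 higher over all genes and 16 adjusted over the list alone (median 0.50, adjusted p = 1.8e-06; adjusted p = 0.0855 with an estimated correlation). IFI44 (1.34 ± 0.13), PARP9 (1.40 ± 0.14) and SAMD9 (1.71 ± 0.17) rose among them. The list test with an estimated correlation gave adjusted p = 0.0155 without both libraries that stand apart. Of 30 G1/S genes 15 rose and 2 fell over all genes, and 16 rose and 2 fell adjusted over the list alone (median 0.36, adjusted p = 0.000248; adjusted p = 0.452 with an estimated correlation). Of 47 replisome genes 14 rose and 4 fell over all genes, and 15 rose and 4 fell adjusted over the list alone (median 0.19, adjusted p = 0.00694; adjusted p = 0.75 with an estimated correlation). That median was 0.32 after quantile normalization, and 0.11 without both libraries that stand apart (adjusted p = 0.0626). Of 45 genes of G2 and mitosis 16 fell and 1 rose under either adjustment (median -0.25, adjusted p = 0.000937; adjusted p = 0.75 with an estimated correlation). The call was lost after quantile normalization (median -0.03, adjusted p = 0.419). Inflammatory genes counted 8 lower and 1 higher of 16 under either adjustment (median -0.54, adjusted p = 0.00432; adjusted p = 0.595 with an estimated correlation). Immediate early genes counted 11 lower and 2 higher of 27 under either adjustment (median -0.42, adjusted p = 0.00234; adjusted p = 0.576 with an estimated correlation). In all, 4854 genes differed by limma's test, 2423 higher and 2431 lower. Leaving out DMSO non-released replicate 1 or 2 gave 2896 and 2400. Without replicate 2 CCNB1 missed the threshold (-0.59, adjusted p = 0.0668). CDKN1A differed by 0.15 ± 0.55 (adjusted p = 0.862) with 15 libraries and rose by 1.03 without DMSO asynchronous replicate 3 (adjusted p = 8.6e-05). Its adjusted p over all alternatives ran from 1.25e-06 to 0.943.

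S-phase cells against asynchronous cells, again with DMSO, gave the 4 h after release against cycling cells. The vitamin D hydroxylase gene CYP24A1 (2.33 ± 0.11 SE, n = 3 and 3, adjusted p = 1.03e-07), RGS4, a regulator of G protein signalling (2.28 ± 0.31, adjusted p = 0.000283), and the linker histone gene HIST1H1A (2.15 ± 0.19, adjusted p = 1.81e-05) rose. The snRNA transcription factor gene SNAPC1 fell by 1.60 ± 0.17 (adjusted p = 5.83e-05) and PTX3 by 1.36 ± 0.21 (adjusted p = 0.000728). CCNE2 rose by 0.49 ± 0.12 (adjusted p = 0.00949; 0.101 in the compared groups alone) and CDC20 fell by 0.87 ± 0.11 (adjusted p = 0.000192). Of 42 histone genes 36 rose over all genes and 37 adjusted over the list alone (median 1.24, adjusted p = 3.06e-18; adjusted p = 0.333 with an estimated correlation). Of 30 ribosome biogenesis and MYC target genes 27 fell over all genes and 28 adjusted over the list alone (median -0.53, adjusted p = 4.91e-14; adjusted p = 0.188 with an estimated correlation), UTP20 (-0.79 ± 0.08) and RRP12 (-0.88 ± 0.09) first. Of 23 interferon genes 8 rose over all genes and 10 adjusted over the list alone (median 0.31, adjusted p = 2.4e-05; adjusted p = 0.133 with an estimated correlation). Its median was 0.20 after quantile normalization and 0.57 under the stricter filter, and without both libraries that stand apart adjusted p was 0.0136 with an estimated correlation. Of 23 sterol synthesis genes 6 fell and 1 rose over all genes, and 8 fell and 1 rose adjusted over the list alone (median -0.25, adjusted p = 0.00547; adjusted p = 0.662 with an estimated correlation, and a median of -0.16 with 0.0631 after quantile normalization). Of 45 genes of G2 and mitosis 11 fell and 1 rose under either adjustment (median -0.17, adjusted p = 0.0156; adjusted p = 0.858 with an estimated correlation), lost after quantile normalization (median -0.05, adjusted p = 0.557) and under the stricter filter (0.0642). Of the fork protection list 13 of 44 rose and 3 fell over all genes, and 15 rose and 3 fell adjusted over the list alone, with no call for the list (median 0.06, adjusted p = 0.133). In all, 3955 genes differed by limma's test, 2012 higher and 1943 lower, of which 3208 were among the 4524 called without both libraries that stand apart. In the compared groups alone 1010 did, 693 higher and 317 lower. CDKN1A (-0.32 ± 0.49, adjusted p = 0.666) and MDM2 (-0.53 ± 0.42, adjusted p = 0.373) turned direction without DMSO asynchronous replicate 3, to 0.57 (adjusted p = 0.00415) and 0.23 (adjusted p = 0.104). Adjusted p over all alternatives ran from 0.000109 to 0.833 and from 0.00498 to 0.569.

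S-phase against non-released cells gave the change from the block to 4 h after it. Replication-dependent histone genes rose together, 39 of 42 over all genes and 40 adjusted over the list alone (median 2.44, adjusted p = 3.92e-59; adjusted p = 0.0561 with an estimated correlation). HIST1H2BJ stood at 3.92 ± 0.31 (SE, n = 3 and 2, adjusted p = 1e-05), HIST1H2AI at 3.02 ± 0.20 (adjusted p = 3.11e-06) and HIST1H3A at 3.16 ± 0.27 (adjusted p = 1.38e-05). These genes are near-identical copies, so reads of one can be counted for another, and the values of single members are uncertain, as is that of ZXDA, which has a close copy. The zinc finger gene ZXDA (-1.98 ± 0.16), the kinase anchor gene AKAP5 (-1.51 ± 0.21) and the co-receptor gene TGFBR3 (-1.42 ± 0.12) fell, as did CCNE2 (-0.91 ± 0.13, adjusted p = 0.00112) and E2F2 (-1.18 ± 0.16, adjusted p = 0.000706). Inflammatory genes counted 9 of 16 higher over all genes and 11 adjusted over the list alone (median 0.74, adjusted p = 1.68e-08; adjusted p = 0.234 with an estimated correlation). The cytokine genes IL11 (2.05 ± 0.32) and LIF (1.05 ± 0.18) were among them. Immediate early genes counted 9 of 27 over all genes and 15 adjusted over the list alone (median 0.46, adjusted p = 1.47e-08; adjusted p = 0.237 with an estimated correlation), DUSP5 (1.69 ± 0.25) among them. Ribosome biogenesis and MYC targets counted 7 of 30 higher over all genes and 10 adjusted over the list alone (median 0.30, adjusted p = 2.52e-07; adjusted p = 0.404 with an estimated correlation), MYC among them (1.13 ± 0.14). They counted 20 without both libraries that stand apart. Of 30 G1/S genes 3 fell over all genes and 7 adjusted over the list alone (median -0.23, adjusted p = 2.69e-05; adjusted p = 0.404 with an estimated correlation), with a median of -0.15 without both libraries that stand apart. In all, 1000 genes differed by limma's test, 587 higher and 413 lower. The count was 2028 without both libraries that stand apart and 335 in the compared groups alone. Leaving out DMSO non-released replicate 1 or 2 gave 277 and 233.

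**Figure D4:**
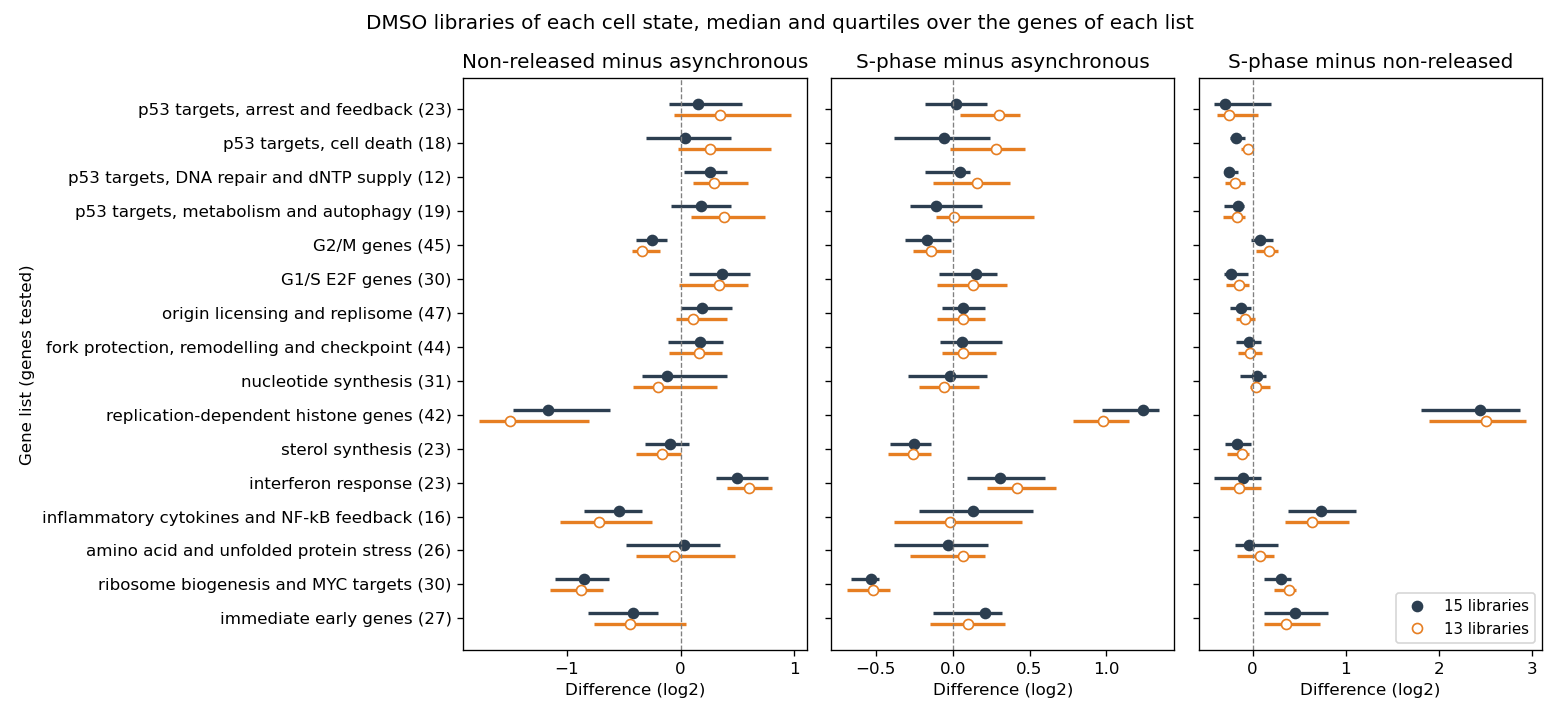
Median difference between cell states in DMSO libraries (log2, horizontal axes) over the genes of each fixed list (vertical axis, number of genes tested in brackets), with quartiles as bars, from all 15 libraries (filled) and from 13 (open). The 42 histone genes have medians of -1.16 in non-released and 1.24 in S-phase cells against asynchronous cells, and 2.44 in S-phase against non-released cells.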

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

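The tests of read counts, of epithelial markers in DMSO asynchronous replicate 3, of label exchange, of position between DMSO and Nutlin, of length and GC content and of library splits were chosen after the results they test were seen. Those of luminal breast and colon markers, of depth and of epithelial markers in DMSO S-phase replicate 2 had predictions written before their values were computed, though after the files had been seen.

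The response to Nutlin differed between states for 18 gene lists by the preset test, and for 0 with an estimated correlation, while 15 of the 18 also passed without both libraries that stand apart. Between S-phase and asynchronous cells the median differences of the responses were 0.37 for G1/S genes (adjusted p = 1.97e-16; 0.0675 with an estimated correlation), 0.24 for genes of G2 and mitosis (2.73e-07; 0.576), 0.21 for the replisome (7.17e-08; 0.404), 0.11 for fork protection (0.00651; 0.404) and 0.39 for histone genes (1.48e-08; 0.576), the last 0.59 without both libraries that stand apart (adjusted p = 6.04e-20; 0.268). Between non-released and asynchronous cells they were 0.27 for G1/S genes (1.55e-19; 0.0561), 0.19 for genes of G2 and mitosis (3.26e-13; 0.404), 0.14 for the replisome (2.76e-05; 0.576), 0.12 for fork protection (0.000119; 0.256), 0.20 for histone genes (1.81e-06; 0.662) and 0.47 for immediate early genes (7.81e-19; 0.0561). The histone value was 0.46 without both libraries that stand apart (adjusted p = 7.41e-25; 0.22 with an estimated correlation). The arrest and feedback targets gave -0.10 (0.00546; 0.404), -0.05 after quantile normalization (adjusted p = 0.169), and -0.29 without both libraries that stand apart (adjusted p = 8.95e-17; 0.0292 with an estimated correlation). Between S-phase and non-released cells the medians were 0.30 for the arrest and feedback targets (0.0374; 0.576), 0.11 for G1/S genes (0.0366; 0.717), 0.12 for the replisome (0.0122; 0.783), 0.18 for histone genes (0.024; 0.876), -0.16 for inflammatory genes (0.00652; 0.612) and -0.41 for immediate early genes (6.22e-14; 0.0979). Without both libraries that stand apart the G1/S, replisome and histone medians between S-phase and non-released cells were 0.05, 0.04 and 0.09 (adjusted p = 0.236, 0.244 and 0.156). That of the arrest and feedback targets was 0.15 (adjusted p = 1.75e-06; 0.167 with an estimated correlation), and its call with 15 libraries was lost after quantile normalization (adjusted p = 0.246), as was that of G1/S genes (0.0502). In that fit of 13 libraries 3 single genes passed, for non-released against asynchronous cells: BTG2 (-1.04, adjusted p = 0.00294), SESN1 (-0.78, adjusted p = 0.011) and TP53INP1 (-1.11, adjusted p = 0.00294). Leaving out DMSO asynchronous replicate 3, set apart by its high p53 targets, enlarges the asynchronous response of such targets. These 3 results, and the -0.29 of the arrest and feedback targets, are therefore no independent test.

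The library labelled DMSO asynchronous replicate 3 was set apart by its high p53 targets. An exchange of labels with a Nutlin library predicts a Nutlin asynchronous library among the DMSO values, and 0 of 3 lay nearer to DMSO replicates 1 and 2. Nutlin-treated U2OS cells under a DMSO label predict a position near 1 for genes that Nutlin raises in the other states, where 0 is DMSO and 1 is Nutlin. The median position over 291 genes was 0.18, under the bound of 0.5, with quartiles of -0.19 and 0.73 and 49 genes above 1. Those genes were called without this library. The choice was changed after a first value of 0.00 over 105 genes had been seen, and that value is not used, since its genes came from the fit that includes this library, which leaves out genes in which it stands high. RNA of another cell type predicts its markers higher there than in every other library. So were 13 of 18 epithelial markers (binomial p = 3.2e-12) and 12 of 13 luminal breast markers (binomial p = 9.4e-14). This held for 2 of 5 colon markers (binomial p = 0.0388), 0 of 3 liver and 0 of 5 blood markers. Not all of the 12 were absent from the other libraries. KRT8, KRT18 and SLC39A6 reached 8762.7, 8967.5 and 1838.4 normalised reads elsewhere, against 15142.6, 10509.5 and 2758.6 there. The library may therefore hold RNA of luminal breast cells beside or in place of some U2OS RNA, and no genotype was tested. Whether p53 was active in such cells was not tested either.

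The library labelled DMSO S-phase replicate 2 was set apart by its distance from its group. Low depth predicts the same spread in replicate 1 thinned to 6.05 M reads, whose standard deviation against replicate 3 was 0.205, near the 0.176 of the whole replicate 1 and under the 0.443 of replicate 2. Of the epithelial markers 1 of 18 was highest there (binomial p = 0.711). That count could not have reached most markers, since DMSO asynchronous replicate 3 held 13 of the 18, so it decides nothing. The median of the 8 epithelial markers that entered the test was 6.93 and 6.89 in DMSO S-phase replicates 1 and 3. It was 6.81 in replicate 2, so these markers as a set were not raised in replicate 2. Of bone and mesenchymal markers 4 of 12 were highest there (binomial p = 0.00633), which was not followed further. Transcript length and GC content correlated with the deviation (rho 0.31 and 0.32), and removing both left a standard deviation of 0.335 of 0.396, over the 0.286 set as the bound for the whole cause, so RNA quality or library preparation could explain a part of it.

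In the library labelled DMSO S-phase replicate 3, 133 genes lay midway between whole reads, so a finer smallest step was used, in this library alone. On it 99.1% of genes with reads had an even number, against 49.1 to 51.0% on the whole-read step of the other 14. A whole read is always even on the finer step, so this share is no test apart from the rarity of genes between whole reads. A mean of 2 independent runs predicts near 50% of genes midway between whole reads, and 0.97% were. Counting each read 2 times predicts no odd number, which holds for nearly all genes but not for the 133. A repeated file could thus explain the even numbers only in part, and the 15.93 M reads would then be the number read once.

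Of the 10 splits of the 6 asynchronous libraries into 3 and 3, 1 called at least 351 genes, the real one, and the highest other called 0. For S-phase against asynchronous cells 1 of 10 called at least 3955, and the highest other called 1. With 10 splits no share under 0.05 can be reached.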

How the results depend on the processing

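All alternatives were set before the data were examined, except leaving out both libraries that stand apart and library weights, chosen after. Of 146 named results 2010 repeats kept direction and side of the threshold, 161 lost the call, 24 gained one and 13 turned direction. Of 70 list calls 396 repeats held and 94 were lost, 67 of them with an estimated correlation, and none turned. Causes were not tested beyond the number of libraries or genes.

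Counts for Nutlin in asynchronous cells went from 351 to 202 in the compared groups alone, 72 at a difference of at least 1, 888 without both libraries that stand apart, and 170 to 437 with 1 library left out. In non-released cells 131 became 637, 41, 459 and 22 to 43, and 227 with voom. In S-phase cells 286 became 99, 76, 563 and 88 to 263. The difference between the responses of non-released and asynchronous cells went from 0 to 3 without both. S-phase against asynchronous cells went from 3955 to 1010 in the compared groups alone and 194 at a difference of at least 1. Non-released against asynchronous cells went from 4854 to 390 at a difference of at least 1 and 2400 to 5342 with 1 left out. S-phase against non-released cells went from 1000 to 335, 157, 2028 without both and 233 to 1112.

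Direction turned only in comparisons in which the gene was not called with 15 libraries. With 1 library left out, CCNB1 under Nutlin ran from -0.20 to 0.10 in S-phase cells. For S-phase against asynchronous cells MDM2 ran from -0.93 to 0.23 (0.34 without both) and CDKN1A from -0.76 to 0.57 (0.69 without both). For non-released against asynchronous cells MDM2 ran from -0.55 to 0.62 (0.62 without both, 0.16 after quantile normalization) and CDKN1A from -0.30 to 1.03.

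Replicate numbers were not taken to pair the libraries, since the rule asks every correlation to be over 0.1. Same-numbered deviations correlated at 0.31, 0.14 and 0.07 in asynchronous, 0.32 in non-released and 0.34 and 0.35 in S-phase cells. The only value under 0.1 was that of asynchronous replicate 3, whose DMSO library stands apart, so the rule failed on that pair alone. Of 15 libraries 12 correlated best with their own number, a hint of pairing from the data and not from the labels. The hint is weak. DMSO S-phase replicate 3 could not do so, as no Nutlin S-phase library has its number. In groups of 2 libraries the deviations from the mean mirror each other, so the non-released libraries could only agree or fail together. A replicate block gave 397, 166 and 324 calls for Nutlin in the 3 states and MDM2 at 0.11 in non-released against asynchronous cells. With it MDM2 (2.21, adjusted p = 0.0218) and CDKN1A (2.32, adjusted p = 0.0284) passed under Nutlin in S-phase cells, and SOX4 in asynchronous cells did not (adjusted p = 0.0532). With the block the list calls for interferon genes under Nutlin in non-released cells (adjusted p = 0.0501), histone genes in the S-phase against non-released response (0.15), and G2 and mitosis (0.0654) and sterol synthesis (0.115) in S-phase against non-released cells were not made, and the repair targets under Nutlin in S-phase cells had a median of 0.26. Equal medians shifted differences by at most 0.023. For Nutlin in asynchronous cells they still gave 298 higher and 53 lower calls, against 273 and 78 with the values as deposited. Quantile normalization gave 259 and 60 there. Library weights ran from 0.107 to 37.8 and did not converge, and were dropped after their counts were seen, 8 of 9 moved: 2611, 884 and 802 for Nutlin in asynchronous, non-released and S-phase cells, 25, 11 and 0 for S-phase against asynchronous, non-released against asynchronous and S-phase against non-released responses, and 9756, 8653 and 5902 for the same pairs of states. Depth limits DMSO S-phase replicate 2 most, with 0 reads meaning under 0.496 counts per M reads.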

Other observations

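The tests behind these values were set before the data were examined, except those without both libraries that stand apart, which were chosen after, as was the showing of GDF15.

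Several lists not described above moved between states in DMSO cells. From the block to S-phase, DNA repair and metabolism targets of p53 had medians of -0.25 and -0.16 (adjusted p = 0.00526 and 0.00652; adjusted p = 0.416 and 0.536 with an estimated correlation). Replisome genes had -0.12 (adjusted p = 0.00234; adjusted p = 0.717 with an estimated correlation and 0.0544 without both libraries that stand apart, and a median of -0.19 after quantile normalization), and ORC1 and PCNA (-0.46 ± 0.11) fell. Sterol synthesis genes had -0.17 and genes of G2 and mitosis 0.08 (adjusted p = 0.047 and 0.0452; adjusted p = 0.781 and 0.876 with an estimated correlation). The sterol call was lost without both libraries that stand apart (median -0.11, adjusted p = 0.0545) and with a replicate block. That of G2 and mitosis was lost after quantile normalization (median 0.00, adjusted p = 0.62), with equal medians (0.0541), under the stricter filter (0.0613) and with a replicate block. Its median was 0.18 without both libraries (adjusted p = 6.36e-05, and adjusted p = 0.562 with an estimated correlation). The interferon gene IFIT1 fell by 1.22 ± 0.21 (adjusted p = 0.00375), with no call for its list (adjusted p = 0.0991). Bone and mesenchymal markers had a median of 0.34 in S-phase against asynchronous cells (adjusted p = 0.0251; adjusted p = 0.513 with an estimated correlation), and 0.08 without both libraries that stand apart (adjusted p = 0.239). In S-phase against asynchronous cells the ribonucleotide reductase gene RRM2 rose by 0.84 ± 0.12 (adjusted p = 0.000331) and DHODH fell by 0.82, with 5 of 31 nucleotide synthesis genes higher and 7 lower over all genes, 6 and 8 adjusted over the list alone (list adjusted p = 0.966).

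In S-phase cells under Nutlin, ribosome biogenesis genes and MYC targets had a median of -0.08 (adjusted p = 0.137), and -0.14 without both libraries that stand apart (adjusted p = 0.000142; adjusted p = 0.307 with an estimated correlation). The arrest and feedback targets had medians of 0.02 in S-phase and 0.15 in non-released against asynchronous DMSO cells (adjusted p = 0.596 and 0.276). Without both libraries these were 0.30 and 0.35 (adjusted p = 0.00274 and 0.00141; adjusted p = 0.307 and 0.296 with an estimated correlation).

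Among blood cell markers ITGAM rose with Nutlin in S-phase cells (0.71 ± 0.13, adjusted p = 0.00988), with the list median at -0.06 and the list test pointing up (adjusted p = 0.411). GDF15, a secreted p53 target, stood at 7.19, 7.05 and 11.76 in the DMSO asynchronous libraries and from 9.03 to 9.23 in the Nutlin asynchronous libraries.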
